A study of Mus musculus with 6 samples.

How the data were processed

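RNA was measured by sequencing in 6 libraries from mouse intestinal tumour organoids, which the labels describe as AKP organoids derived from tumours grown in vivo. The labels put 3 libraries in a Control group and 3 in a group whose genotype is SOX17KO, made with CRISPR-Cas9. Per the labels' protocols, RNA was purified with a column kit and made into directional libraries after poly(A) selection. The submitters' processing notes name Bowtie, RSEM and the mouse build mm9, with no versions; the annotation, the strand setting and any filters are not given in the sources used here.

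The authors deposited 1 table of expected counts, the estimated reads per gene that RSEM gives, for 23224 genes in 6 columns, 1 per library, and every column was matched to a sample by its name. Between 26.6% and 30.3% of a library's values were not whole, and the values were rounded to whole numbers before testing. Totals were 27503254, 21238718 and 26466544 in Control replicates 1, 2 and 3 and 24765258, 23411787 and 18290912 in SOX17KO replicates 1, 2 and 3. The ribosomal RNA gene Rn45s took 2.10% of the counts in Control replicate 2 and between 0.389% and 0.547% in each of the other libraries. Counts came from reads without molecular identifiers, so a counting interval covers counting error only.

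The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter (filterByExpr, minimum count 10, minimum total 15), 1 coefficient for genotype and Benjamini-Hochberg adjustment over the 12137 genes tested. Genes at an adjusted p below 0.05 were called, and those with a log2 fold change of at least 1 in size were counted as 2-fold. The standard error of a log2 fold change is its size divided by the square root of F. CPM are counts scaled by the TMM-adjusted library sizes, given as mean and SD over 3 libraries. The 27 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 tested members, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The labels do not say whether libraries of a group came from separate cultures or clones, so the p-values measure the spread between these samples.

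The test, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Sox17, Ifngr1, Lgr5 and Cd274; the 6 largest called changes each way with groups that did not overlap and at least 5 CPM in the higher group; up to 3 called members of each of 5 primary lists and up to 2 of each other list, by smallest p; the most abundant member of each technical list and of each list with no call. Other genes named were chosen after their values were seen, and 1 gene that the rule takes is not reported here. The alternatives were RLE size factors, library totals only, no low-count filter, at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0 on all genes with counts and its own independent filtering, limma-voom, unrounded values, the replicate number as a block, and each library left out in turn. Counts outside shifted chromosome regions, limma-voom with library quality weights, and camera without the genes of those regions were added after seeing the data, as were DESeq2 on the genes of the main filter and camera with an estimated correlation leaving aside SOX17KO replicate 1 or 2. The list members Muc2, Hmgcs1, Ccl28, Ifi27 and Sh2d6 were not analysed here.

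Gene order was scanned after the data had been seen. Names, chromosomes and the order of neighbours came from RefSeq on GRCm38.p6, a later build than mm9, so no coordinates are given; 12017 of the tested genes (99.0%) were matched. Over 9316 genes with a mean log2 CPM above 3, a running median of 21 genes was taken of each library's log2 CPM (prior count 2) minus the Control mean. A region needed a running median of at least 0.3 in size, the same way in all 3 SOX17KO libraries, over at least 10 genes. Gene order was shuffled 1000 times with a fixed seed.

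The procedure was tested on simulated counts for SOX17KO against Control with 12055 genes in the step. It recovered 20.9% of genes changed 1.5-fold, 64.6% of those changed 2-fold and 93.8% of those changed 4-fold, with 10 false among 127 calls. Of 100 unchanged lists, camera gave an unadjusted p below 0.05 for 1, camera with an estimated correlation for 0 and fry for 4. Simulated genes were drawn independently of each other, with the same dispersion in both groups, and list members were picked at random. The simulation therefore does not check the list tests where members of a list vary together. The region scan found 58 of 60 genes of an implanted region and 1 gene outside it. The implanted shift was -1 in log2 CPM in each SOX17KO library, larger in size than the median of either region reported below. Recovery of smaller shifts was not tested. Figures were drawn with matplotlib 3.10.9.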

Results

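The data were gene expression profiles of AKP organoids, a mouse model of intestinal tumours, in 3 Control libraries and 3 libraries labelled SOX17KO, with 18290912 to 27503254 counts each. The comparison addressed the role of SOX17, an endoderm transcription factor, in colon cancer. Sox17 itself was at 34.4, 34.5 and 34.2 CPM in the Control libraries and at 33.8, 41.9 and 45.1 CPM in the libraries labelled SOX17KO. Its mean was 34.4 ± 0.15 CPM in Control and 40.3 ± 5.82 CPM in SOX17KO (SD, n = 3), and its log2 fold change of 0.23 ± 0.12 (SE) did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.345). Its level was therefore not lower and does not check the labels. Without SOX17KO replicate 1 it was higher, with a log2 fold change of 0.34 (edgeR adjusted p = 0.0113).

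In the libraries labelled SOX17KO, 446 genes were higher and 388 lower, of which 243 and 179 changed at least 2-fold. The largest increases by rule were in Gm2083, Pla2g2a, Smoc2, Trf, Ank2 and Rbpms. Pla2g2a, a secreted phospholipase of Paneth cells, was at 0.0726 ± 0.0614 CPM in Control and 13.3 ± 9.38 CPM in SOX17KO. Trf, which encodes transferrin, was at 0.340 ± 0.109 and 26.2 ± 17.98 CPM, and Rbpms, an RNA-binding protein gene, at 0.166 ± 0.107 and 10.6 ± 5.54 CPM. Ank2 was at 25.6 CPM in SOX17KO replicate 1 and at 1.14 and 3.44 CPM in the other two. Gm2083 belongs to the major urinary protein family, whose near-identical copies share reads, and its value is uncertain; with 3.36 expected counts over the Control libraries, its ratio of 1177 has a 95% counting interval of 333 to 4723. Among decreases, the neighbouring G protein subunit genes Gng11 and Gngt1 fell from 18.4 ± 1.43 to 0.111 ± 0.192 CPM and from 13.9 ± 1.88 to 0.231 ± 0.204 CPM; they and Pdzrn3 lie on chromosome 6, where 79.5% of scanned genes were lower. Pdzrn3 fell from 62.8 ± 4.09 to 8.07 ± 4.89 CPM and Bnipl from 14.6 ± 1.17 to 2.57 ± 1.12 CPM. Hspb1, a small heat shock protein gene, fell from 43.5 ± 3.22 to 6.92 ± 1.84 CPM, and 2310043J07Rik from 144.1 ± 10.5 to 13.3 ± 1.80 CPM; both lie in a region of chromosome 5 where most genes were lower. All 834 called genes had groups that did not overlap, as did 28.2% of all tested genes, against 10% by chance. SOX17KO replicate 1 lay apart, with correlations of log2 CPM of 0.960 and 0.963 to the other two SOX17KO libraries against 0.986 between those. SOX17KO replicates 2 and 3 correlated more closely with each Control library (0.968 to 0.970) than with SOX17KO replicate 1. Leaving out 1 Control library lowered the calls to 197, 192 and 202 (without replicates 1, 2 and 3), and leaving out SOX17KO replicate 1 raised them to 2708. Without SOX17KO replicates 2 and 3 there were 759 and 673 calls. Ank2 was not called without any one of the Control libraries or SOX17KO replicate 3, and Gm2083 and Trf were not called without Control replicate 1 (highest edgeR adjusted p 0.204, 0.0581 and 0.0601). With limma-voom Ank2, Gm2083, Trf and Smoc2 were not called (adjusted p = 0.246, 0.0653, 0.0969 and 0.0924), nor was Ank2 with library totals only (edgeR adjusted p = 0.0507). Without SOX17KO replicate 1 the log2 fold change was 3.76 in place of 5.93 for Ank2 and 6.85 in place of 7.52 for Pla2g2a. That of Pla2g2a was 8.30 without Control replicate 2. That of Rbpms was 6.57 in place of 5.90 without Control replicate 1, and that of Pdzrn3 -3.57 in place of -2.98 without SOX17KO replicate 3. Gng11 had counts in SOX17KO in replicate 3 alone and Gngt1 in replicates 1 and 3, and Gm2083 was at 15.2, 22.8 and 94.1 CPM in SOX17KO replicates 1, 2 and 3.

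**Figure D1:**
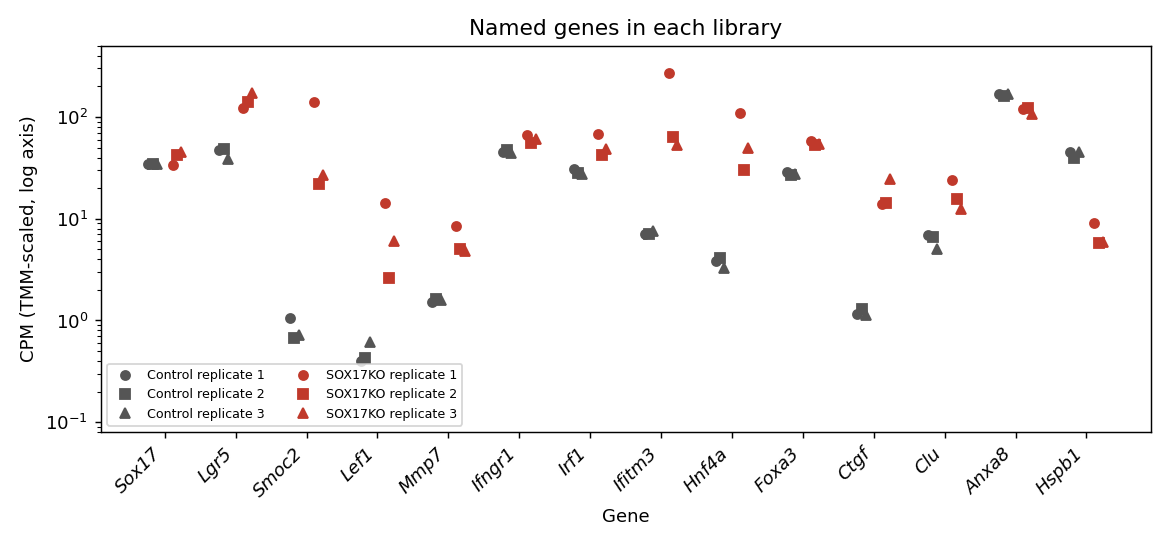
CPM on a log axis of 14 genes in each library, grey for Control and red for SOX17KO, with a circle, square and triangle for replicates 1, 2 and 3. Sox17 overlaps between the groups, Lgr5 lies at 38.3 to 48.4 CPM in Control and 123.2 to 172.9 CPM in SOX17KO, and Smoc2 and Ifitm3 are highest in SOX17KO replicate 1.

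Of 16 tested intestinal stem cell markers, 2 rose, none fell and 14 were not called; adjusted over the list alone, 5 were higher and 1 lower. DESeq2 called 5 higher and 1 lower and limma-voom 1 higher. EdgeR called 7 higher and 2 lower without SOX17KO replicate 1, and 1 higher without any one Control library. Lgr5, the receptor that marks crypt base stem cells, rose from 44.8 ± 5.68 to 145.2 ± 25.3 CPM, with a log2 fold change of 1.70 ± 0.15 (edgeR adjusted p = 0.00171). Smoc2, another crypt base gene, rose from 0.814 ± 0.206 to 62.7 ± 66.4 CPM, with 139.4 CPM in SOX17KO replicate 1 and 21.9 and 26.9 CPM in the other two. Of 16 tested Wnt pathway targets, 4 rose and none fell, with 6 higher and 2 lower adjusted over the list alone. DESeq2 called 8 higher and 2 lower and limma-voom 2 higher. With edgeR, 6 higher and 2 lower were called without SOX17KO replicate 1, 7 higher and 1 lower without SOX17KO replicate 2, and 1 higher without any one Control library. Lef1, a transcription factor of the pathway, rose from 0.479 ± 0.113 to 7.62 ± 5.94 CPM, with 14.2, 2.63 and 6.04 CPM in SOX17KO replicates 1, 2 and 3, and Mmp7, a secreted protease, from 1.58 ± 0.0552 to 6.09 ± 2.04 CPM. Both lists passed camera with an adjusted p of 0.00412, and neither did with an estimated correlation (adjusted p = 0.405 for each). They share Lgr5, Axin2, Rnf43, Znrf3, Tnfrsf19 and Cd44, and Lgr5 counts among the calls of both, so their tests are not independent. Mmp7 is also a member of the Paneth cell and antimicrobial list. Camera called 7 lists between the groups and up to 10 in other splits of the 6 libraries. Lgr5 was called without each library in turn, while Smoc2, Lef1 and Mmp7 were not called without any one of the Control libraries (highest edgeR adjusted p 0.0802, 0.109 and 0.0691), nor Smoc2 and Lef1 with limma-voom (adjusted p = 0.0924 and 0.0782). The log2 fold change without SOX17KO replicate 1 was 4.87 in place of 6.25 for Smoc2 and 3.14 in place of 3.98 for Lef1.

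Of 32 interferon gamma signalling genes 20 were tested, of which 3 rose, none fell and 17 were not called, with 6 higher adjusted over the list alone. The untested members had at most 31 counts per group. Among them the induced chemokine genes Cxcl9, Cxcl10 and Cxcl11, chosen after their values were seen, had at most 11.01. DESeq2 called 4 higher and limma-voom 3 higher. EdgeR called 4 higher and 1 lower without SOX17KO replicate 1, and 0 without any one Control library or SOX17KO replicate 3. Ifngr1, a subunit of the interferon gamma receptor, rose from 45.6 ± 1.55 to 60.9 ± 5.39 CPM, a log2 fold change of 0.42 ± 0.09 (edgeR adjusted p = 0.0371). Jak2, the kinase bound to that receptor, rose from 35.1 ± 1.52 to 46.9 ± 3.53 CPM, and Irf1, a transcription factor it induces, from 28.8 ± 1.58 to 52.8 ± 13.9 CPM. Cd274, which encodes PD-L1, was at 0.732 ± 0.183 and 0.505 ± 0.405 CPM, with a log2 fold change of -0.48 (95% interval -1.80 to 0.84; edgeR adjusted p = 0.728). The list passed camera narrowly (adjusted p = 0.0427) and not with an estimated correlation (adjusted p = 0.645). It also missed the threshold without Control replicate 3 and without each SOX17KO library (highest camera adjusted p 0.110), and Ifngr1, Jak2 and Irf1 were not called without any one of the Control libraries or SOX17KO replicate 3 (highest edgeR adjusted p 0.193, 0.197 and 0.160). With library totals only none of the 3 was called (edgeR adjusted p = 0.0647, 0.0535 and 0.0513), nor was the list (camera adjusted p = 0.0659); with no low-count filter Jak2 and the list were not called either (edgeR adjusted p = 0.0519 and camera adjusted p = 0.0512).

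Of 17 tested genes of MHC class I presentation, 0 were called over all genes and 0 adjusted over the list alone with edgeR (camera adjusted p = 0.246). Among the 17, 13 had a positive log2 fold change and 4 an unadjusted edgeR p below 0.05. The list's median log2 fold change was 0.042 and its mean 0.24. DESeq2 called 3 higher and 0 lower, limma-voom called 0, and edgeR called 4 higher and 0 lower without SOX17KO replicate 1. Calr, an endoplasmic reticulum chaperone, was at 962.4 ± 44.7 and 990.7 ± 78.7 CPM. The only tested gene of MHC class II presentation was Rfx5, at 14.6 ± 1.24 and 19.7 ± 1.65 CPM (edgeR adjusted p = 0.0756); it was called higher without SOX17KO replicate 1 (edgeR adjusted p = 0.0330) and with DESeq2 (adjusted p = 0.0381). Type I interferon and antiviral genes rose in 3 of 17 tested members and fell in none, with 5 higher and 1 lower adjusted over the list alone. DESeq2 called 5 higher and limma-voom 3 higher. With edgeR, 6 higher and 1 lower were called without SOX17KO replicate 1, 2 higher without SOX17KO replicate 2, and 0 without any one Control library. Ifitm3, a restriction factor against viral entry, was at 7.25 ± 0.348 CPM in Control and at 271 CPM in SOX17KO replicate 1 and 62.9 and 52.8 CPM in the other two, and Ddx58, which encodes the RNA sensor RIG-I, rose from 12.9 ± 1.01 to 22.5 ± 1.55 CPM. This list passed camera (adjusted p = 0.0295) and not with an estimated correlation (adjusted p = 0.617). Without Control replicate 3 it missed the threshold (camera adjusted p = 0.0637), and Ifitm3 and Ddx58 were not called without any one of the Control libraries (highest edgeR adjusted p 0.107 and 0.0569). The log2 fold change of Ifitm3 was 2.99 in place of 4.15 without SOX17KO replicate 1.

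Fetal-like and regenerative markers moved both ways. Of 22 tested members 3 rose and 3 fell, with 4 higher and 8 lower adjusted over the list alone, and the list did not pass camera (adjusted p = 0.490); its median log2 fold change was -0.24 and its mean 0.11. DESeq2 called 4 higher and 8 lower and limma-voom 3 higher and 3 lower. EdgeR called 7 higher and 9 lower without SOX17KO replicate 1, and 1 higher and 0 lower without any one Control library. Ctgf, a matricellular protein gene, rose from 1.20 ± 0.0824 to 17.6 ± 6.16 CPM (log2 fold change 3.87 ± 0.28, edgeR adjusted p = 0.000791). Clu, which encodes clusterin, rose from 6.19 ± 1.03 to 17.4 ± 6.12 CPM, and Anxa8, an annexin gene, fell from 167.0 ± 4.08 to 116.8 ± 7.38 CPM. Ctgf was called without each library in turn, while Clu and Anxa8 were not called without any one of the Control libraries (highest edgeR adjusted p 0.114 and 0.0769).

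**Figure D2:**
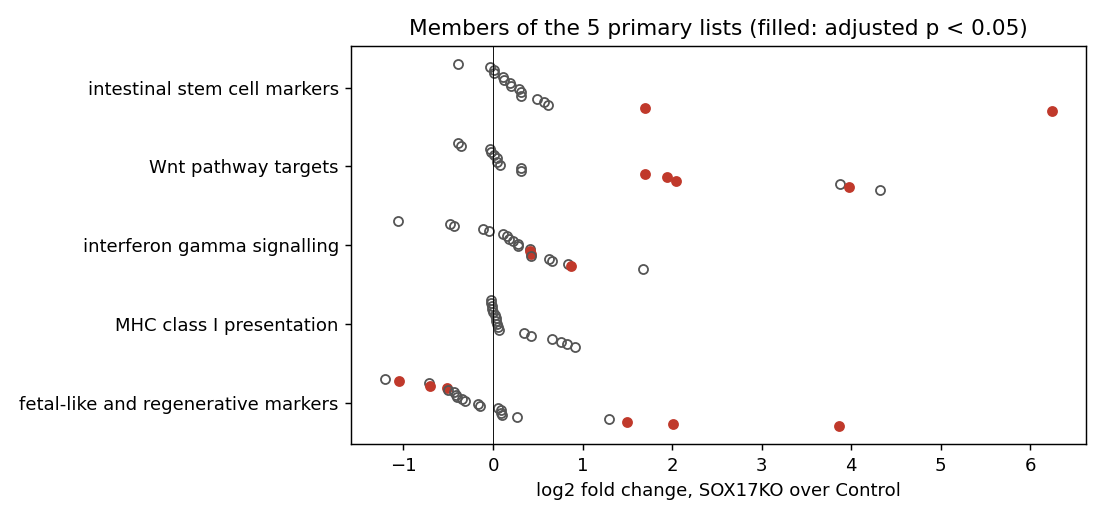
Log2 fold change of SOX17KO over Control for each tested member of the 5 primary lists, with called genes filled. Smoc2 lies farthest to the right at 6.25, and no member of the MHC class I list is called.

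Genes of differentiated lineages included several increases. Of 10 Paneth cell and antimicrobial genes, 3 were abundant enough to test and all 3 rose (camera adjusted p = 1.95e-07, and adjusted p = 0.228 with an estimated correlation): Pla2g2a, Mmp7 and Itln1, a lectin gene that went from 1.01 ± 0.0511 to 5.37 ± 1.48 CPM. Among the untested members, Lyz1, Ang4, Defa24, Defa17 and Defa22 had 0 counts in every library and Reg3g and Reg3b had 0 in Control and 2 and 3 in SOX17KO; these were named after their values were seen, and Pla2g2a had 5 counts over the Control libraries. Hnf4a, a regulator of enterocyte identity, rose from 3.74 ± 0.388 to 63.2 ± 41.8 CPM, with 110.1, 29.98 and 49.4 CPM in SOX17KO replicates 1, 2 and 3. Without replicate 1 its log2 fold change was 3.41 in place of 4.08. It was the 1 called gene among the 5 tested of 19 enterocyte markers (camera adjusted p = 0.630). Of the enterocyte markers too low to test, Car1 had 14 counts over Control and 610.84 over SOX17KO, 523.84 of them in its highest library. The others had at most 30 counts per group. Foxa3, a transcription factor of goblet cells, rose from 27.8 ± 1.08 to 55.2 ± 3.09 CPM. It was the 1 call among the 6 tested of 15 goblet and secretory markers (camera adjusted p = 0.433). For that list DESeq2 called 3 higher and 1 lower, as did edgeR without SOX17KO replicate 1. Its tested members summed to 210.1, 487.6 and 406.2 CPM in SOX17KO replicates 1, 2 and 3, against 292.6 to 335.7 CPM in Control. Of 13 tuft cell markers 3 were tested, and of these Ptgs1, a cyclooxygenase gene, fell from 120.7 ± 2.34 to 68.9 ± 8.93 CPM (camera adjusted p = 0.469). Among tuft markers too low to test, Pou2f3 and Il25 had at most 1 count in any library. Trpm5 had 12 counts over Control and 6 over SOX17KO, and Dclk1 had 6 and 64, 60 of them in its highest library. DESeq2 called 1 higher and 1 lower, and edgeR called 2 higher and 1 lower without SOX17KO replicate 1. The 3 tested tuft markers summed to 250.0, 912.1 and 745.9 CPM in SOX17KO replicates 1, 2 and 3, against 595.3 to 649.8 CPM in Control. Of 11 gastric epithelial markers 3 were tested, and the others had at most 30 counts per group. Among the tested ones Gkn1 rose but stayed at 0.526 ± 0.168 CPM (camera adjusted p = 0.0157, and adjusted p = 0.552 with an estimated correlation). Most of the counts of this list were from Tff1, a trefoil factor gene chosen after its values were seen, at 25.0 to 29.1 CPM in Control and at 34.8, 177.0 and 153.6 CPM in SOX17KO replicates 1, 2 and 3 (edgeR adjusted p = 0.0633). Summed over the 3 tested members, SOX17KO replicate 1 was at 47.3 CPM and replicates 2 and 3 at 190.5 and 196.3 CPM, against 31.7 to 37.1 CPM in Control. Without SOX17KO replicate 1 the gastric list had a camera adjusted p of 8.84e-09 (adjusted p = 0.150 with an estimated correlation). No enteroendocrine marker was abundant enough to test. Hnf4a was not called without Control replicate 1 or 3, Ptgs1 without Control replicate 1 or 2, and Gkn1 without any one library but SOX17KO replicate 1 (highest edgeR adjusted p 0.0526, 0.0525 and 0.183). The gastric list missed the threshold without Control replicate 2, SOX17KO replicate 2 or SOX17KO replicate 3 (camera adjusted p = 0.0768, 0.0712 and 0.110), and it and Gkn1 did so with no low-count filter (camera adjusted p = 0.154 and edgeR adjusted p = 0.0560).

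Of 17 tested cholesterol synthesis genes, 3 fell and 1 rose, and 2 had a positive log2 fold change, with 10 lower and 1 higher adjusted over the list alone. DESeq2 called 8 lower and 1 higher and limma-voom 3 lower. With edgeR, 10 lower and 1 higher were called without SOX17KO replicate 1, 0 lower and 1 higher without SOX17KO replicate 3, and 0 without any one Control library. Fdft1, which encodes squalene synthase, fell from 289.4 ± 1.91 to 216.6 ± 12.2 CPM. The list passed camera as lower (adjusted p = 0.00445) and not with an estimated correlation (adjusted p = 0.502); its median log2 fold change was -0.28 and its mean 0.05. Without SOX17KO replicate 2 it missed the threshold (camera adjusted p = 0.0654), and Fdft1 was not called without any one of the Control libraries or SOX17KO replicate 3 (highest edgeR adjusted p 0.136).

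Genes of neighbouring positions shifted together in the libraries labelled SOX17KO. On chromosome 5, 166 tested genes from Wbscr16 to Rpl21 had a median log2 fold change of -0.75 (quartiles -1.28 and -0.51), with 113 called lower and 1 higher. On chromosome 12, 129 genes from Angel1 to Crip1 had a median of 0.46, with 51 called higher and 1 lower. Median differences from the Control mean in SOX17KO replicates 1, 2 and 3 were -0.90, -0.76 and -0.83 on chromosome 5 and 0.40, 0.48 and 0.49 on chromosome 12. These regions held 2.43% of tested genes, 29.4% of all lower calls and 35.2% of those at least 2-fold lower. Chromosome 6 formed no region by the rule; its 434 scanned genes had a median log2 fold change of -0.25, and 79.5% were lower. Outside the regions 394 genes were higher and 274 lower, and 238 and 116 at least 2-fold. None of 1000 shuffles of gene order gave a region (p = 0.000999, the smallest they can give in this permutation test), and no Control library against the other two gave one. Scanned singly, SOX17KO replicates 1, 2 and 3 had 10, 9 and 3 regions.

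**Figure D3:**
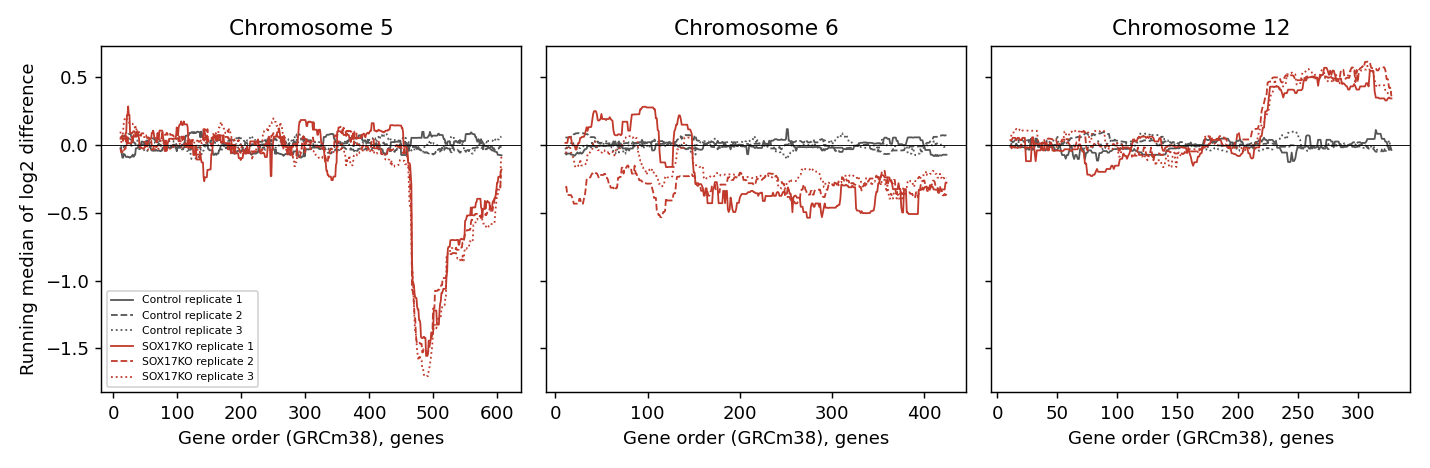
Running median over 21 genes of each library's log2 difference against gene order on chromosomes 5, 6 and 12; red lines are SOX17KO libraries against the Control mean and grey lines Control libraries against the other two. The red lines leave 0 together toward the end of chromosomes 5 and 12, while the grey lines reach at most 0.172 in size.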

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

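Counts outside the shifted regions, library quality weights, DESeq2 on the genes of the main test, camera without the genes of those regions, and estimated correlations leaving aside SOX17KO replicate 1 or 2 were chosen after seeing the data. Under RLE factors, library totals only, no filter, the stricter filter, limma-voom and unrounded values, all 4 counts of called genes stayed within 1.5 times, and no called gene changed sign under any alternative. Single calls were lost among named genes: limma-voom ended those of Ank2, Etv5, Gm2083, Lef1, Smoc2 and Trf (adjusted p 0.0562 to 0.246), library totals only those of Ank2, Etv5, Ifngr1, Irf1 and Jak2 (0.0507 to 0.0686), no filter those of Epcam, Gkn1 and Jak2 (0.0519 to 0.0707), and DESeq2 that of Gkn1 (0.0966). DESeq2's Wald test, run on 17039 genes with its own filtering, called 770 higher, 667 lower and 388 at least 2-fold higher; on the 12137 genes of the main test it called 748 higher and 677 lower, and Gkn1 was not called there either (adjusted p = 0.0951). Leaving out 1 library gave 97 to 1453 genes higher, 94 to 1255 lower, 80 to 431 at least 2-fold higher and 79 to 293 at least 2-fold lower; the lows are without a Control library and the highs without SOX17KO replicate 1. Quality weights gave 1111, 951, 393 and 273, with a weight of 0.137 for SOX17KO replicate 1, and counting outside the regions left 116 at least 2-fold lower. With the replicate number as a block, 183 genes were higher and 143 lower, 153 and 117 at least 2-fold, and 12 named genes were not called (Anxa8, Cxcl1, Ddx58, Dll1, Dll4, Epcam, Etv5, Fdft1, Gkn1, Ifngr1, Irf1 and Jak2, adjusted p 0.0507 to 0.192). Same-numbered libraries deviated with correlations of -0.19, -0.05 and -0.18, and libraries of unlike number with -0.06 to 0.17. These values give no sign of pairing by number, but so few libraries cannot exclude it. The log2 fold change of Sox17 was 0.14 to 0.34 with 1 library left out and 0.30 with quality weights, past the threshold with these weights and without SOX17KO replicate 1. The adjusted p of interferon gamma signalling was 0.0659 with library totals only, 0.0512 with no filter, 0.0607 with the block, 0.645 with an estimated correlation, 0.0541 with fry and 0.0368 to 0.110 with 1 library left out. With an estimated correlation, stem cell markers and Wnt targets each had an adjusted p of 0.405; leaving aside SOX17KO replicate 1 or 2 as well, these lists and interferon gamma signalling each had 0.509 or 0.567. Fry ended the gastric call (adjusted p = 0.0758) and called enterocyte and goblet markers (0.0161 and 0.0237). Of 37 called named genes, 13 were called without each library in turn and 24 were lost without at least 1 Control library. Leaving a library out means fewer samples, but 192 to 202 genes were called without a Control library. Without SOX17KO replicates 2 and 3 there were 759 and 673 calls, so sample number alone does not account for the fall. The biological coefficient of variation between pairs of libraries was 4.70% to 7.34% within Control and 12.6% to 29.5% within SOX17KO. The main test shares its dispersion for a gene between these unlike groups. Whether this lowered the calls, and the cause of the other changes, was not tested. Directions reversed as follows. With 1 library left out, the log2 fold change ranged from -0.15 to 0.12 for Asns, -0.0053 to 0.10 for Calr, -0.15 to 0.46 for Cd68, -0.11 to 0.43 for Egfl7 and -0.26 to 0.22 for Junb, and adjusted p ranged from 0.765 to 0.954 for endothelial markers, 0.0446 to 0.765 for hypoxia genes, 0.742 to 0.978 for immediate early genes, 2.69e-05 to 0.844 for stress response genes, 0.103 to 0.978 for MAPK targets, 0.531 to 0.954 for Notch genes, 0.506 to 0.844 for p53 targets, 0.531 to 0.932 for TGF-beta genes and 0.169 to 0.571 for tuft markers. Cytokines and leukocyte markers reversed with no filter (adjusted p = 0.949 each), TGF-beta genes with the stricter filter (0.878), Cd68 with limma-voom (log2 fold change -0.072), and Asns and Junb with quality weights (0.071 and 0.15). With an estimated correlation leaving aside SOX17KO replicate 1, adjusted p of reversed lists was 0.934 for Notch and TGF-beta genes, 0.652 for hypoxia genes and tuft markers, 0.772 for immediate early genes and 0.633 for p53 targets, and leaving aside replicate 2 it was 0.987 for endothelial markers, immediate early genes and stress response genes. In data simulated at this depth and number of libraries, 20.9% of 1.5-fold changes were recovered; how much of this depth limits was not separated from the number of libraries.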

Other observations

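Of 13 tested epithelial cytokines and chemokines, 1 rose and 3 fell (camera adjusted p = 0.785): the neutrophil attractant Cxcl5 rose from 1.28 ± 0.255 to 9.22 ± 2.47 CPM and Cxcl1 fell from 11.2 ± 0.670 to 6.40 ± 0.423 CPM. Of 10 tested Notch pathway genes, the ligand Dll4 rose from 0.529 ± 0.0814 to 2.34 ± 0.892 CPM and the ligand Dll1 fell from 1.77 ± 0.0520 to 0.746 ± 0.187 CPM (camera adjusted p = 0.883). Car9, a carbonic anhydrase gene induced by hypoxia, rose from 23.9 ± 3.32 to 144.6 ± 79.7 CPM as the 1 call among 16 hypoxia and glycolysis genes (camera adjusted p = 0.785). Etv5 was the 1 call among 15 MAPK targets, at 20.8 ± 0.700 and 32.3 ± 6.21 CPM (camera adjusted p = 0.785), and Epcam the 1 call among 12 tested TGF-beta and epithelial-mesenchymal genes, at 532.5 ± 9.23 and 675.9 ± 1.60 CPM (camera adjusted p = 0.785). Without SOX17KO replicate 1 edgeR called 4 higher and 5 lower of the cytokines, 3 and 2 of the Notch genes, 4 and 1 of the hypoxia genes, 5 and 0 of the MAPK targets and 3 and 2 of the TGF-beta genes. Except for Cxcl5, each of these genes was not called without any one of the Control libraries (highest edgeR adjusted p 0.0914 for Cxcl1, 0.103 for Dll4, 0.159 for Dll1, 0.083 for Car9, 0.198 for Etv5 and 0.207 for Epcam). Dll1 was also not called without SOX17KO replicate 2, Etv5 without SOX17KO replicate 3 and Epcam without either (edgeR adjusted p = 0.0723 for Dll1, 0.0821 for Etv5, 0.0657 and 0.0749 for Epcam). Etv5 was not called with limma-voom or library totals only (adjusted p = 0.0562 and 0.0686), nor Epcam with no low-count filter (edgeR adjusted p = 0.0707).

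No call was made with edgeR among 23 tested proliferation genes, 9 tested endoderm and gut transcription factors, 17 tested p53 targets or 12 tested integrated stress response genes (camera adjusted p = 0.325, 0.785, 0.854 and 0.819). In these lists 3, 3, 4 and 1 genes had an unadjusted p below 0.05, DESeq2 called 1, 3, 2 and 0, limma-voom called 0 in each, and edgeR without SOX17KO replicate 1 called 13, 3, 6 and 7. Of the endoderm factors too low to test, Gata4 had 4 counts over Control and 243 over SOX17KO (127 in its highest library). Cdx1 had 0 and 24, 23 of them in its highest library, and the other untested factors had at most 19 counts per group. These were named after their values were seen. With no low-count filter, edgeR called 1 endoderm factor higher and 0 lower. Mki67 was at 1190 ± 39.1 and 1067 ± 122.6 CPM, Klf4 at 378.2 ± 11.1 and 289.9 ± 30.7, Perp at 317.8 ± 13.6 and 259.3 ± 37.0 and Asns at 460.0 ± 13.1 and 450.7 ± 86.2. Without SOX17KO replicate 1, Klf4 and Mki67 were called lower, with log2 fold changes of -0.31 and -0.26 (edgeR adjusted p = 0.0128 and 0.0261), and Klf4 was also called lower with DESeq2 and with library totals only (adjusted p = 0.00600 and 0.0477). Without SOX17KO replicate 1, the lists of proliferation genes (lower), integrated stress response genes (higher) and hypoxia genes (higher) passed camera with adjusted p of 6.76e-06, 2.69e-05 and 0.0446, and with an estimated correlation had adjusted p = 0.523, 0.150 and 0.652. Without SOX17KO replicate 2, the endoderm and gut transcription factors passed camera as higher (adjusted p = 0.0447, and adjusted p = 0.567 with an estimated correlation). Of 12 immediate early and heat shock genes 1 was higher and 1 lower (camera adjusted p = 0.883), and without SOX17KO replicate 1 edgeR called 3 higher and 2 lower. Junb was at 172.2 ± 5.81 and 164.1 ± 64.5 CPM, and was called higher without SOX17KO replicate 1 (log2 fold change 0.22, edgeR adjusted p = 0.0375). Among markers of other cells, none of 3 leukocyte, 1 fibroblast and 3 endothelial genes tested was called with edgeR, DESeq2 or limma-voom or had an unadjusted edgeR p below 0.05, and 1 leukocyte gene was called without SOX17KO replicate 1 (camera adjusted p = 0.819 for leukocyte and 0.883 for endothelial markers), with Cd68 at 9.06 ± 1.42 and 9.89 ± 4.60 CPM, Tagln at 1.35 ± 0.256 and 1.78 ± 0.387 and Egfl7 at 2.75 ± 0.469 and 3.16 ± 1.13.

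Tests of other cell types, of swapped libraries, of regulation, of an edit that keeps the transcript and of chromosome 6 as a whole were chosen after the results were seen, as were the regions themselves. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05: the real split called 834 genes and the highest of the others 0, and 1 split reached the real count. For the lists, the real split called 7 with camera and the highest of the others 10, and 5 of the 10 splits called as many, so at the preset correlation camera called as many lists in splits that mix the groups.

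The shifted regions may reflect a difference in DNA copy number between the groups. If so, genes too low to define a region would follow it; the share doing so was 87.9% on chromosome 5 (29 of 33, exact 95% interval 71.8% to 96.6%) and 74.1% on chromosome 12 (20 of 27, 53.7% to 88.9%), a lowest share of 0.741 against a bound of 0.65 that the interval on chromosome 12 still includes, with 50.1% of low genes elsewhere being lower. Chromosome 6 was named with the others when that test was written but formed no region. Of its low genes, 97 of 152 were lower, a share of 0.638 (55.6% to 71.4%). As written, the test of all of chromosome 6 counts a share of 0.65 or less against copy number. The interval includes 0.65, as it does on chromosome 12, so neither share decides. The tables argue against GC content, since genes elsewhere with the same GC content shifted by at most 0.0489 of the regions' medians. Regulation following SOX17 deletion stays open, and DNA was not analysed here. A region was defined by a shift in all 3 SOX17KO libraries, so its presence in each of them was fixed by the rule and decides nothing. Scanned singly, SOX17KO replicates 1, 2 and 3 had 10, 9 and 3 regions and each Control library had 0.

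SOX17KO replicate 1 lay apart from the other two, with a correlation of log2 CPM of 0.960 and 0.963 to them against 0.986 between them. SOX17KO replicates 2 and 3 were closer to each Control library (0.968 to 0.970) than to SOX17KO replicate 1. Thinning all libraries to the same total left 0.992 of the difference of SOX17KO replicate 1 from them. Its summed CPM of markers of other cells were 0.557 of the higher of SOX17KO replicates 2 and 3. Regions were also sought where replicate 1 differed from the mean of replicates 2 and 3, whichever of them had moved from Control. Of the 439 genes at least 2-fold apart, 4.10% lay in such regions, which held 1.28% of scanned genes. These values argue against depth, those cell types and such regions as the whole cause. Of the 6 such regions, those on chromosome 6 were higher in replicate 1 than in replicates 2 and 3, and those on chromosomes 2, 11, 15 and 19 lower. Ndrg1, chosen after its values were seen, was at 98.1 CPM in replicate 1 and 624.7 and 991.7 CPM in the other two, and at 551.9 to 682.1 CPM in Control. Whether replicate 1 was another clone or was grown differently stays open and was not tested.

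Sox17 transcripts were not lower in the libraries labelled SOX17KO. A swap of single libraries between the groups is argued against by the correlations, since the lowest within Control was 0.994 and the highest between the groups 0.970. An edit that keeps the transcript in place could leave a log2 fold change such as the 0.23 seen, but gene counts cannot show the edited sequence. An exchange of all labels between the groups also stays open, and no biological explanation was tested. With Sox17 at 33.8 to 45.1 CPM over all libraries, no exchange of labels would give a group without its transcript.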
